A study of Drosophila melanogaster with 20 samples.

How the data were processed

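EcR binding was measured by CUT&RUN in wing, leg and salivary gland, in supernatant and pellet fractions. Per the labels, at least 50 salivary glands or 90 wings or legs were dissected, and libraries were made with the Takara ThruPLEX kit. The submitters' processing notes name Bowtie2 2.3.4.1, SAMtools 1.9, Picard 2.2.4, bedtools 2.26, MACS2 2.1.2, R 3.5.2 and DESeq2 with no version, and the build dm6, without saying in which order or with which settings they were used. Names of the deposited peak lists say that replicates were merged, reads trimmed, duplicates removed and fragments of 20 to 120 bp kept. Names of the single peaks point to the merged wing IgG libraries as the control for all 6 lists, the gland's included, which no label states.

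For each peak the authors deposited a fold enrichment, a linear ratio over background, and a q-value as its −log10. Each peak also has a summit offset, an other kind of value in bp that the authors deposited. In the 3 tables the authors deposited a mean normalised read count per site, which is a signal over the libraries of the fit. The log2 fold change and its standard error are the authors' deposited values, and so is the Wald statistic, a score. The p-value and the adjusted p-value are the authors' deposited values from DESeq2, per the submitters' processing notes and the form of the tables. Which libraries and fractions entered each fit is not given in the sources used here. The score was not exactly the fold change over its error (ratio of 0.175 to 1.55, median near 1.00). Calls therefore rest on the deposited adjusted p, apart from those after centring or adjusted over a list alone. For centring, the median fold change of the chromosome arms over the deposited standard error was subtracted from the score. Normal p-values with Benjamini-Hochberg adjustment followed, so centred calls are approximate. An adjusted p listed as 0 is a limit of printing. The authors' overlap flags between sites and lists were equal to the overlap computed here at all 3463 sites.

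The tables hold no counts per library, so the planned count test was replaced by the authors' own adjusted p, with 0.05 as the threshold. Depth per library is unknown, and the precision of a fold change is its deposited standard error, with medians of 0.587 for wing and gland, 0.615 for leg and gland and 0.53 for wing and leg. Sites without an adjusted p, 4 in each comparison with the gland and 136 between wing and leg, could not be called. They count as not called in the totals of the gene lists. After centring, sites with an unadjusted p were adjusted together, so centred and deposited calls may not rest on the same sites. No peak or score was tested in size between lists.

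Overlap was at least 1 bp. Shares have exact (Clopper-Pearson) 95% intervals, and 1000 shuffles within chromosomes gave the share by chance. Supernatant peaks of the 3 tissues were merged and classed by tissue, and each merged region took the summit of its peak with the highest fold enrichment in any list. Peak strength was compared within a list by a permutation test with 100000 permutations, and location and direction by Fisher's exact test, all two-sided. These tests treat peaks, regions or sites as independent, though they are not replicates. Benjamini-Hochberg adjustment was made over the 8 tests of location, over lists and tissues, and over lists and comparisons. A gene of a list was bound where a summit lay in its span or within 2000 bp, against 10000 random lists matched on span in 20 bins among 13947 genes (one-sided). Direction was the median over a list's genes of the mean log2 fold change of their sites, against 10000 random lists matched on the number of sites (two-sided), for lists with at least 3 genes with sites. The shared gland libraries were simulated 1000 times with no effect.

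Gene spans came from a RefSeq gene table of 17872 genes on the same assembly, 13962 of them coding. It holds no strand, exons or introns, so sites are given as inside a span or by their distance from it. Coordinates are 1-based. The 17 gene lists covered the ecdysone response, ecdysone metabolism and uptake, salivary glue, gland identity and secretion, cell death and autophagy, wing identity, leg identity, Hox genes, disc signalling, disc eversion and matrix, cuticle, cell cycle, and markers of fat body, haemocytes, muscle, trachea and neurons. All members were found in the gene table under their own or an older symbol, except 1 fat body name.

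The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 sites of each direction with the largest log2 fold change among those called with a mean at or above the table's median, 1 per gene within 5000 bp. It added called members of the gene lists and the 10 strongest peaks of each supernatant list and of the class shared by all tissues, which were ranked by the highest fold enrichment in any of the 3 lists. The strongest peaks of 1 tissue alone were named after the data were seen. So were the alternatives that keep only the chromosome arms or centre the fold changes on them. The arms end at 22 Mb on 2L, 23 Mb on 3L and 22 Mb on X, begin at 6 Mb on 2R and 4.5 Mb on 3R, and leave out chromosomes 4, Y and M.

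The tests were tested on simulated data. With no effect, 2.5% of bound-list tests, 5.5% of direction tests (both on 3000 features) and 7.0% of strength tests (on 800) had p under 0.05, and with a known effect 99.5%, 95.0% and 100%. Of 1000 simulated peaks, the 40.0% that were shared were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The planned search for EcR motifs was not run, since no genome sequence was used here. The 8 IgG libraries were not analysed here.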

Results

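The series measured where the ecdysone receptor EcR, the nuclear receptor that carries the signal of the moulting hormone ecdysone, sits on chromatin in 3 tissues of the fruit fly. Wings, legs and salivary glands were dissected from female wandering larvae, 6 hours before puparium formation, when wings and legs exist as imaginal discs. EcR carried a tag with a Flag epitope on 1 chromosome, over a deletion on the other. CUT&RUN was done with an anti-Flag antibody: an antibody tethers a nuclease that releases DNA fragments around the bound protein. For each tissue the fragments released into the supernatant and those left in the pellet were sequenced as separate libraries, with 2 replicates per tissue and fraction, 12 libraries in all. Another 8 libraries were made with IgG, 6 from wild-type wings and 2 from salivary glands of the tagged genotype, and they were not analysed here. Names of the single peaks point to the merged wing IgG libraries as the control of all 6 peak lists. If so, gland peaks and their fold enrichments were called against the background of another tissue. The labels do not say whether replicates came from separate dissections, so the authors' p-values measure the spread between these libraries, which may be technical. Peaks came as 6 lists, 1 per tissue and fraction, each from merged replicates, and the differences between tissues as 3 tables over the same 3463 sites. The depth of each library is unknown, and the normalised read count averaged over libraries had a median of 9.59 per site in the authors' deposited tables, with quartiles of 5.58 and 20.1. Coordinates are on dm6.

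Several of the strongest EcR peaks lay at genes of the ecdysone response. In the wing the highest fold enrichment over background in the authors' supernatant list, 111, belonged to a peak on 3L from 5627664 to 5628389, 2993 bp outside the span of Blimp-1, a transcriptional repressor induced by ecdysone. The same peak had a fold enrichment of 156 in the leg list and 16.0 in the salivary gland list. The highest leg value, 160, belonged to a peak on 3L from 5621807 to 5622423, with no coding gene within 5000 bp. Peaks inside Hr4, a nuclear receptor gene of the ecdysone cascade on chromosome X, were among the 10 strongest of every list. The one from 1947901 to 1948584 reached 95.8 in the wing, 123 in the leg and 51.3 in the gland. Hsp27, a small heat shock gene, had a peak 547 bp away with a fold enrichment of 90.4 in the leg. Eip75B, an early ecdysone-induced nuclear receptor gene, had 2 peaks among the 10 strongest of the wing, at 72.4 and 69.6. In the gland list the ecdysone-induced Eip74EF reached 46.0, a peak in the overlapping spans of br and Mur2B reached 41.2, and a peak in beat-Ib reached 43.6. The top 4 gland peaks were on chromosome M or near the centromere of 2R, in a stretch with no coding gene span, with fold enrichments of 68.4 to 157. Fold enrichments are the authors' values per peak and rank peaks within a list only.

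The supernatant lists held 1442 wing, 1596 leg and 1174 salivary gland peaks, and the pellet lists 1545, 1010 and 936. Median peak widths were 130 to 160 bp. Of the supernatant peaks, 61.9% in the wing, 64.8% in the leg and 77.6% in the gland had their summit inside a coding gene span. These lists come from merged replicates and have no replicate error, so their lengths were not tested against each other. In the wing, 1021 of 1442 supernatant peaks overlapped a pellet peak by at least 1 bp, 70.8% (exact 95% interval 68.4 to 73.1). The share was 38.4% (36.0 to 40.8) in the leg and 58.9% (56.0 to 61.7) in the gland. Pellet peaks moved at random within chromosomes overlapped at most 1.28% of supernatant peaks in 1000 shuffles in any of these tissues. The intervals treat peaks as independent and cover counting error only.

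The question of how far EcR binds the same places in different tissues was addressed with the supernatant lists. Their peaks merged into 2734 regions, of which 354 (12.9%, 11.7 to 14.3) had a peak in all 3 tissues. Wing and leg together, without the gland, accounted for 586 regions (21.4%). The gland alone had 702 (25.7%), the leg alone 564 (20.6%) and the wing alone 439 (16.1%). Regions shared by the gland with only 1 of the discs were few, 42 with the wing and 47 with the leg. Of the wing peaks, 66.4% (63.9 to 68.9) overlapped a leg peak, and of the leg peaks 27.0% (24.8 to 29.3) overlapped a gland peak, beside 28.6% of the wing peaks. Of the gland peaks, 423 of 1174 overlapped a wing peak and the same number a leg peak, 36.0% (33.3 to 38.9) each. No shuffle gave more than 2.13% in any pair of supernatant lists. In the pellet lists the wing alone took 29.7% of the merged regions and the leg alone 10.2%, beside 16.1% and 20.6% in the supernatant.

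**Figure D1:**
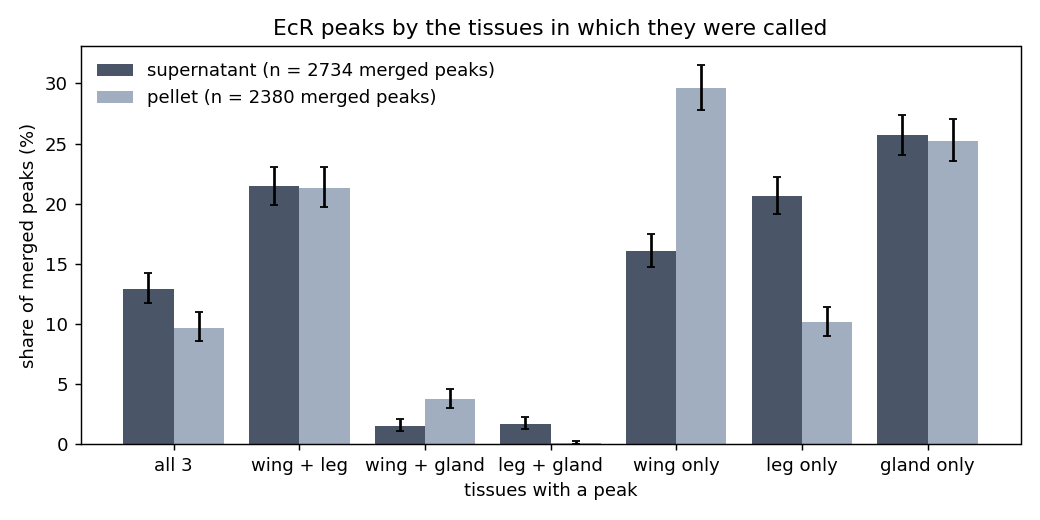
Share of merged EcR peaks (percent) by the tissues in which a peak was called, for the supernatant (2734 merged peaks) and pellet (2380 merged peaks) lists, with exact 95% binomial intervals as error bars. Peaks of the gland alone make up 25.7% of the supernatant regions and 25.3% of the pellet regions, while regions shared by the gland and 1 disc stay under 4%.

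Regions occupied in all 3 tissues carried stronger peaks. In the wing list their median fold enrichment was 13.0, against 4.79 for peaks of the wing alone. The medians were 14.6 and 5.04 in the leg list, and 8.92 and 6.03 in the gland list, where the ratio of medians was 1.48 against 2.71 in the wing and 2.89 in the leg. Permutation tests within each list (two-sided, 100000 permutations) gave p = 1e-05 in all 3 lists, the smallest they can give. The classes were made from the same peak calls, and passing the caller in 3 lists by itself selects strong peaks. The tests cannot separate that selection from a difference in binding. Among the strongest peaks called in 1 tissue alone were peaks at ap, the dorsal selector gene of the wing, at tkv, a receptor for the morphogen Dpp, and at ex, a gene of the Hippo growth pathway, in the wing (12.9, 12.2 and 12.1). The strongest peaks of the leg alone lay in Atg1, which starts autophagy (21.2), in Eip75B (18.1) and in osp (16.1). Those of the gland alone lay in Nt5b (32.5), in scramb1, a phospholipid scramblase gene, in Raf, a kinase gene (26.0), and in the ecdysone-induced E23 (22.7) and Eip75B (22.5). A peak in 1 list alone is not a tested difference. Between wing and leg, the sites at ap, ex and osp were called in the authors' deposited table. The Atg1 site (-1.40, adjusted p = 0.182 in the authors' deposited table) and those at tkv were not.

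Gland-only regions also lay more often at the edges of genes. Their summits were within 500 bp of an end of a coding gene span in 138 of 702 regions (19.7%), against 41 of 354 (11.6%) for regions of all 3 tissues (Fisher's exact test, two-sided, p = 0.000926, adjusted p = 0.00247 over 8 tests). For regions of the wing alone the share was 10.7% and for those of the leg alone 8.69%, and neither passed (adjusted p = 0.734 and 0.228). Pooled over all regions of 1 tissue the share was 13.7% (adjusted p = 0.347). Summits lay inside a coding gene span in 73.2% of regions of all 3 tissues, in 53.5% of those of the wing alone (adjusted p = 1.02e-07), in 62.2% of those of the leg alone (adjusted p = 0.00247) and in 80.9% of those of the gland alone (adjusted p = 0.00884). The gene table used has no strand, so either end of a span was counted in place of the transcription start. With only peaks of a -log10 q of 10 or more, no difference in this paragraph passed except that between all 3 tissues and the wing alone near gene ends (14.2% against 4.49%, adjusted p = 0.0217).

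Genes of the ecdysone response were bound in every tissue far beyond random gene lists. Of 28 such genes, 18 had a wing supernatant peak in or within 2000 bp of their span, 21 a leg peak and 19 a gland peak, where random lists matched on span held 5.14, 6.00 and 5.16 on average. Permutation p was 1e-04, the smallest 10000 lists can give, and adjusted p was 0.0017 in each tissue. EcR itself, br, Eip74EF, Eip75B, Eip78C, Hr3, Hr4, Hr39, Hr78, Kr-h1, Blimp-1, vri and tai were bound in all 3 tissues. ImpE1 and ImpE3, ecdysone-inducible genes of imaginal discs, had peaks in the 2 disc lists, and Eip63F-1 in the gland list. The list of disc signalling genes was bound beyond chance in the discs, with 11 of 25 genes in the wing (4.17 by chance, adjusted p = 0.00714) and 12 in the leg (4.86 by chance, adjusted p = 0.00714). In the gland 4 of its genes were bound against 4.48 by chance (adjusted p = 0.895). It includes ptc, brk, tkv, nkd, fz2 and Delta, which act in the Hedgehog, Dpp, Wnt and Notch pathways. Cell death and autophagy genes passed in the leg (5 of 18, 1.38 by chance, adjusted p = 0.035, with hid, Diap1, Atg1, Atg9 and E2f1). The only Atg9 site, with a mean normalised count of 43.6, had no adjusted p in any of the authors' deposited tables. Gland binding at this list, 5 of 18 genes, had an adjusted p of 0.0954 and included Dark, Atg5 and Atg13. In the gland, 4 of 10 fat body marker genes were bound, Lsp1beta, Lsp2, Fbp1 and Fbp2 (0.719 by chance, adjusted p = 0.0263), against 1 in each disc. The leg call for cell death genes was lost on the chromosome arms alone (adjusted p = 0.0517), with equally long lists (adjusted p = 0.0848) and with pellet peaks (adjusted p = 0.151), the leg call for disc signalling with equally long lists (adjusted p = 0.0554) and the gland call for fat body genes with pellet peaks (adjusted p = 0.112). The differences between tissues in these counts were not themselves tested.

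The other lists did not pass in any tissue at an adjusted p of 0.05. No gene of the 13 salivary glue genes, the main secreted products of the larval gland, had a supernatant peak in any tissue, and 1 of them, Sgs1, had a pellet peak in the leg. Of 18 genes of gland identity and secretion, 2 were bound in the gland, fkh and CrebA. Wing identity genes were bound in 6, 4 and 1 of 22 cases in wing, leg and gland, and leg identity genes in 6, 9 and 5 of 24. Of 8 Hox genes, 2 had a supernatant peak in the leg, Antp and Ubx (2.07 by chance), and none in the wing or gland. Each of them also had 1 site higher in the wing than in the gland in the authors' deposited table (1.69 and 2.50). For disc eversion and matrix genes the counts were 6, 6 and 4 of 17, for cuticle genes 2, 1 and 1 of 18, and for cell cycle genes 2, 3 and 1 of 16. Ecdysone metabolism and uptake genes had 3 of 14 in each tissue, phtm, spok and Oatp74D. Marker lists of other cell types gave 0, 1 and 1 of 10 for haemocytes, 2, 3 and 1 of 10 for muscle, 2, 3 and 2 of 10 for trachea and 0, 2 and 0 of 11 for neurons.

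**Figure D2:**
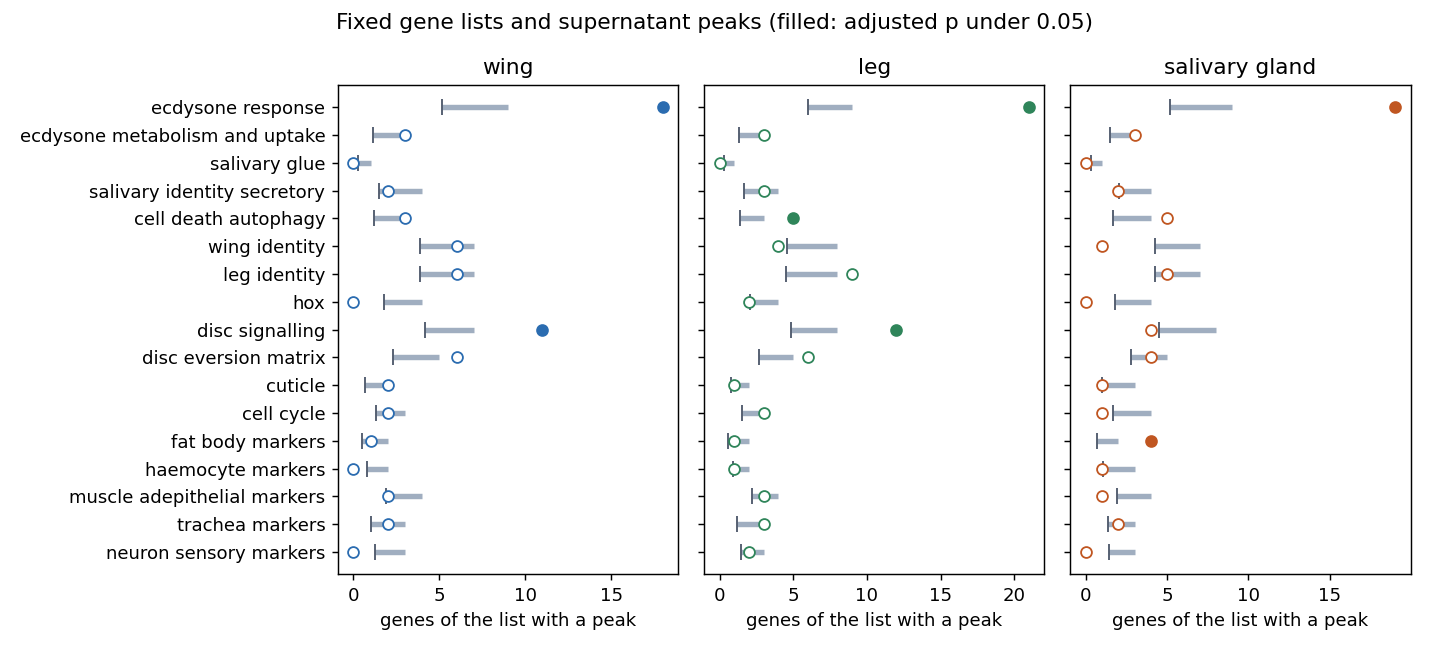
Number of genes of each of 17 fixed lists with a supernatant peak in wing, leg and salivary gland (circles, filled where the adjusted p is under 0.05). Vertical ticks give the mean of 10000 random lists matched on gene span and grey bars reach to their 95th percentile. The ecdysone response list lies farthest to the right in all 3 tissues, at 18, 21 and 19 genes.

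Between the wing and the salivary gland, EcR sites differed widely, and the comparison asked which sites distinguish a disc from a gland that is later lost. At 993 sites the authors' deposited table gave higher values in the wing and at 914 in the gland, at an adjusted p under 0.05, together 55.1% of the 3459 sites tested. Higher in the wing were sites at Ppn, which codes for the matrix protein papilin (log2 fold change 4.31, SE 0.76, in the authors' deposited table), inside Eip75B (3.08, SE 0.47), in Sb, a protease gene needed for disc eversion (2.82, SE 0.66), and 4206 bp from kni, a gene of wing vein patterning (2.82, SE 0.65). Others of the 10 largest, here and below taken 1 per gene among called sites with a mean at or above the median of the authors' deposited table, lay in CG9416, mtgo, Msr-110, the overlapping CG1688 and CG1698, 1226 bp from RpL17, and in Myo81F near the centromere of 3R, between 2.78 and 3.62. Higher in the gland were sites in Cul5, a ubiquitin ligase subunit (-5.29, SE 0.71, in the authors' deposited table), Nt5b (-5.21, SE 0.56), scramb1 (-5.01, SE 0.44) and Raf (-4.83, SE 0.54), a fold difference of 39.1 for Cul5. A site inside the EcR gene, on 2R from 6133131 to 6133402, was 22.7-fold higher in the gland in the authors' deposited table (-4.50, SE 0.65, adjusted p = 1.62e-10). Sites 82 bp outside CG42460 and in Cph, gce, a receptor for juvenile hormone, egh and the nested CG33995, CG44000 and CG44001 completed the 10 largest in the authors' deposited table, between -4.70 and -4.39.

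The gene lists were compared by the direction of their sites, and none passed. Of the 50 disc signalling sites, 22 were higher in the wing and 3 in the gland in the authors' deposited table, and the counts adjusted over the list alone were also 22 and 3. The median over its 16 genes with sites was 0.88, against -0.31 for matched random lists, and the permutation p of 0.0066 became 0.257 after adjustment over lists and comparisons. Examples in the authors' deposited table were nkd, an antagonist of Wnt signalling, with 5 of 8 sites higher in the wing, and tkv with 4 of 5. Of the 22 disc eversion sites, 6 were higher in the wing in the authors' deposited table, at Sb, Np, dpy and zip, and 2 in the gland, at RhoGEF2 and sqh. The middle of the RhoGEF2 site lies 468 bp outside its span and 19 bp outside that of Dark, so it counts for both genes. Among cell death and autophagy genes, with 6 sites higher in the wing and 7 in the gland of 24 in the authors' deposited table, both sites at Dark, a subunit of the apoptosome, were higher in the gland (-3.70 and -2.96), as were those at Atg5 (-2.53) and Atg13 (-2.95). Of the 11 sites at genes of gland identity and secretion, 3 were higher in the wing in the authors' deposited table, at CrebA (0.90), Pdi (1.08) and trh (2.37). The 2 higher in the gland were at fkh (-2.80) and sens (-2.33). The only glue gene with a site, Sgs1, had -0.13 and did not pass. Of the wing identity genes, ap had 2 sites higher in the wing (1.41 and 2.05 in the authors' deposited table, in the window near the centromere of 2R, where the median of all 38 sites was 1.44) and ct 1 site higher in the gland (-2.58). At fat body genes 5 of 7 sites were higher in the gland in the authors' deposited table, and 1, 475 bp from Lsp1gamma, was higher in the wing. No list passed the direction test in this comparison, with adjusted p from 0.257 to 0.888. The median log2 fold change of all sites was 0.46. Centred on the chromosome arms, the values gave 814 sites higher in the wing and 974 in the gland, so the side with more calls turned from wing to gland.

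The leg gave a like picture against the gland. At 1024 sites values were higher in the leg and at 786 in the gland in the authors' deposited table, 52.3% of those tested. The largest leg values were again at Ppn (4.24, SE 0.77, in the authors' deposited table), Myo81F (3.91, SE 0.72) and near RpL17 (3.64, SE 0.71), followed by a site 4323 bp from Wnt6 (3.25, SE 0.67). Sites in tkv (2.93, SE 0.41), in Ubx, the Hox gene of the posterior thorax (2.94, SE 0.54), and at CG34347, mrj, RhoU and Unc-76 were also among the 10 largest of the authors' deposited table. On the gland side stood scramb1 (-4.20, SE 0.45, in the authors' deposited table), Keap1, a sensor of oxidative stress (-4.16, SE 0.48), the same EcR site as above (-4.11, SE 0.69) and Fatp3 (-3.96, SE 0.44). The others of the 10 largest gland sites in the authors' deposited table, at Cph, CG42460, Nt5b, Raf, the nested CG33995 group and the overlapping Tpst and CG46311, lay between -4.05 and -3.72.

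Leg identity genes carried 12 sites higher in the leg and 2 in the gland of 30 in the authors' deposited table, 12 and 2 also when adjusted over the list alone. The median over 11 genes was 1.03 against -0.21 for matched lists, and the permutation p of 0.0304 became 0.395 after adjustment. They include hth, a homeobox gene of the proximal leg, with 4 sites of 1.01 to 3.09 in the authors' deposited table, and Lim1, with sites at 2.00 and 1.90. The same list had 7 sites higher in the wing and 2 in the gland in the authors' deposited table of wing and gland, and those at Dll (2.38) and dysf (1.98) were called there and not for the leg. Between wing and leg 1 of its sites, at hth, was called in the authors' deposited table. Adjusted over the list alone, 4 were higher in the leg and 0 in the wing. The list's direction did not pass (permutation test, adjusted p = 0.686). For wing minus leg, 1 site each at Sp1 (-2.32), Lim1 (-1.91) and bab1 (-1.82) had no deposited adjusted p. In the authors' deposited table disc signalling genes had 20 sites higher in the leg and 2 in the gland of 50 (adjusted p = 0.39 for direction), again 20 and 2 adjusted over the list alone. Of the 8 sites at the Hox genes Antp and Ubx, 5 were higher in the leg in the authors' deposited table and none in the gland. At fat body genes 5 of 7 sites were higher in the gland in the authors' deposited table, led by Fbp1 (-2.75, SE 0.75), Fbp2 (-2.29, SE 0.57) and Lsp2 (-2.28, SE 0.72), while the site near Lsp1gamma was higher in the leg (1.90, SE 0.42). No list passed the direction test here either, with adjusted p from 0.39 to 0.888. The median of all sites was 0.63, and with fold changes centred on the chromosome arms the leg side fell from 56.6% to 40.9% of the calls.

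The 2 comparisons with the gland moved together. Of the sites higher in the discs in the authors' deposited tables, 771 were called in both, and of those higher in the gland 737, with 0 sites called in opposite directions. Independent lists of these sizes would share 294 and 207. Across the 3463 sites, which are not independent replicates, Pearson's r was 0.925 and Spearman's rho 0.895. The 2 comparisons share their gland libraries, and simulated values with no effect gave r = 0.595. With no effect next to no site is called in either comparison, so the 0 shared calls of the simulation are no measure for the 771 and 737. The covariance was 2.72 against 0.23 in the simulation, a difference of 2.49. The tables hold no column per library, so the gland libraries could not be split, and part of the excess of shared calls over independent lists may come from sharing them.

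**Figure D3:**
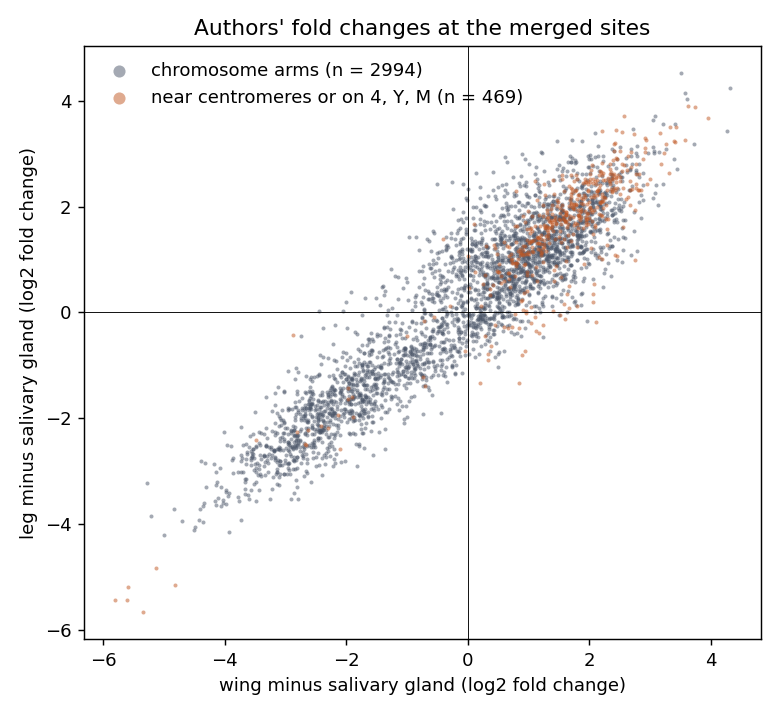
Each point is 1 of the 3463 sites, with the authors' log2 fold change of wing minus salivary gland on the horizontal axis and of leg minus salivary gland on the vertical axis. Orange marks the 469 sites near centromeres or on chromosomes 4, Y and M, whose median is 1.61 for the wing and 1.75 for the leg, and grey the 2994 sites on the arms, with medians of 0.17 and 0.37.

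The peak lists and the tables gave the same direction. Of 1190 sites called in the authors' deposited table of wing and gland and carrying a supernatant peak in 1 of the 2 tissues only, 1189 were higher in the tissue with the peak. For leg and gland it was 1118 of 1120 and for wing and leg 28 of 28 (Fisher's exact test, two-sided, p = 0.000305 for the last, below numerical precision for the others). Having a peak in 1 list did not mean being called. Of the sites with a gland peak and no wing peak 84.3% were called in the authors' deposited table, of those with a wing and no gland peak 56.5%, but 3 of 461 sites with a wing and no leg peak and 25 of 600 with a leg and no wing peak. The sites were the basis of both measures, so this is a description of the files more than independent evidence.

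Within single ecdysone genes, sites higher in the discs lay among sites higher in the gland. The 22 ecdysone response genes with sites carried 201 of them. Against the wing, 78 were higher in the gland and 49 in the wing in the authors' deposited table (78 and 50 adjusted over the list alone), and against the leg 79 and 42 (79 and 44). At 9 genes of the 22, sites of both directions were called between wing and gland. Eip75B, on 3L from 17950953 to 18064696, held 57 sites, of which 16 were higher in the wing and 27 in the gland in the authors' deposited table, from 3.08 to -3.98. At the EcR gene 7 of 8 sites were higher in the gland and 1 in the wing in the authors' deposited table, at br 8 of 13 were higher in the gland and 3 in the wing, and at tai, a coactivator of EcR, 6 of 12 in the gland and none in the wing. ImpE2 (4 of 4 sites), Blimp-1 (3 of 3), ImpE1 (2 of 2) and ImpE3 (1 of 1) had all their sites higher in the wing in the authors' deposited table. Both sites at Eip63F-1 were higher in the gland than in either disc in the authors' deposited tables, and both at Hr78 higher than in the wing, against 1 of them for the leg. The list's median over genes, -0.43 for the wing and -0.38 for the leg, did not stand apart from matched lists (permutation test, adjusted p = 0.666 and 0.603).

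**Figure D4:**
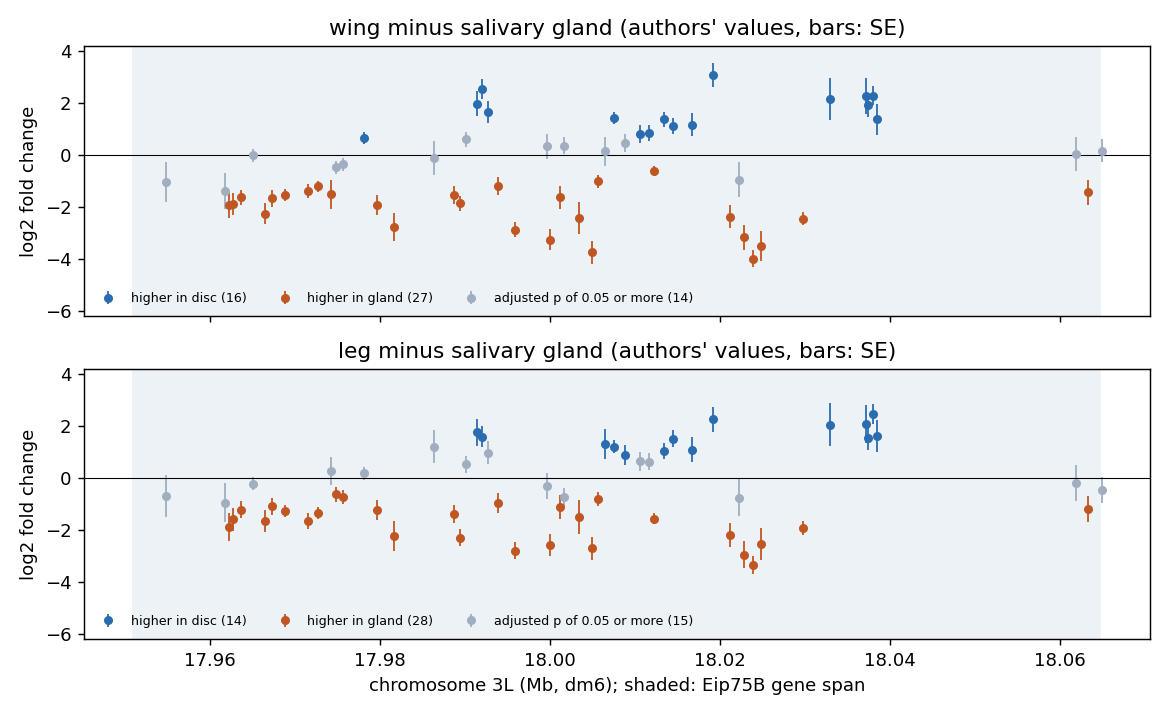
The authors' log2 fold changes (points, bars are standard errors) of the 57 sites at Eip75B along 3L, with wing minus salivary gland above and leg minus salivary gland below, and the gene span shaded. Blue sites were higher in the disc (16 and 14), orange sites higher in the gland (27 and 28), and grey sites did not pass.

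Few sites were called between wing and leg, which does not show that the discs are alike at the others. Both discs give rise to appendages, and the comparison asked where EcR binding parts them. Only 19 sites were higher in the wing and 30 in the leg in the authors' deposited table, 1.47% of the 3327 tested, and at an unadjusted p under 0.05 the counts were 136 and 302. Higher in the wing was a site in ap (log2 fold change 1.39, SE 0.34, adjusted p = 0.00964 in the authors' deposited table), on 2R from 5727148 to 5727398. Also higher in the wing were sites in GV1 (2.12, SE 0.45, in the authors' deposited table), in the overlapping ome and CG4914 (1.71, SE 0.23), in Msr-110, in sick, in ex (1.58, SE 0.39), in CG11905, Phk-3 and Snoo, and 3596 bp from mab-21. Higher in the leg was a site inside Ubx on 3R from 16663517 to 16663898 (-2.32, SE 0.39, adjusted p = 1.54e-06 in the authors' deposited table), with a fold of 5.01. A second Ubx site (-2.74, SE 0.67) and a site 169 bp from hth (-1.76, SE 0.52) were also higher in the leg in the authors' deposited table. A site 2762 bp from disco-r, a zinc finger gene of the ventral appendages, had -2.51 (SE 0.72) in the authors' deposited table, and a site in m, which codes for a zona pellucida domain protein, -2.50 (SE 0.38). Ptip, CG7991, CG34347, Glg1 (a site that also lies within reach of Hr78), Eip78C, osp and CG6398 made up the rest of the 10 largest leg sites in the authors' deposited table, from -2.49 to -1.86. Of the 201 ecdysone response sites 3 were higher in the wing and 3 in the leg, with 4 and 3 adjusted over the list alone. None of the 50 disc signalling sites was called in the authors' deposited table (1 and 1 adjusted over the list alone). For the 8 Hox sites the counts were 0 and 2, and 0 and 3 adjusted over the list alone. The split between wing and leg depends on the centring of the values. Centred on the chromosome arms, whose median was -0.19 beside -0.18 over all sites, 48 sites were higher in the wing and 17 in the leg, so that the wing's share of the calls went from 38.8% to 73.8%, and the sites at disco-r, CG7991, Glg1 and Eip78C were no longer called.

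**Figure D5:**
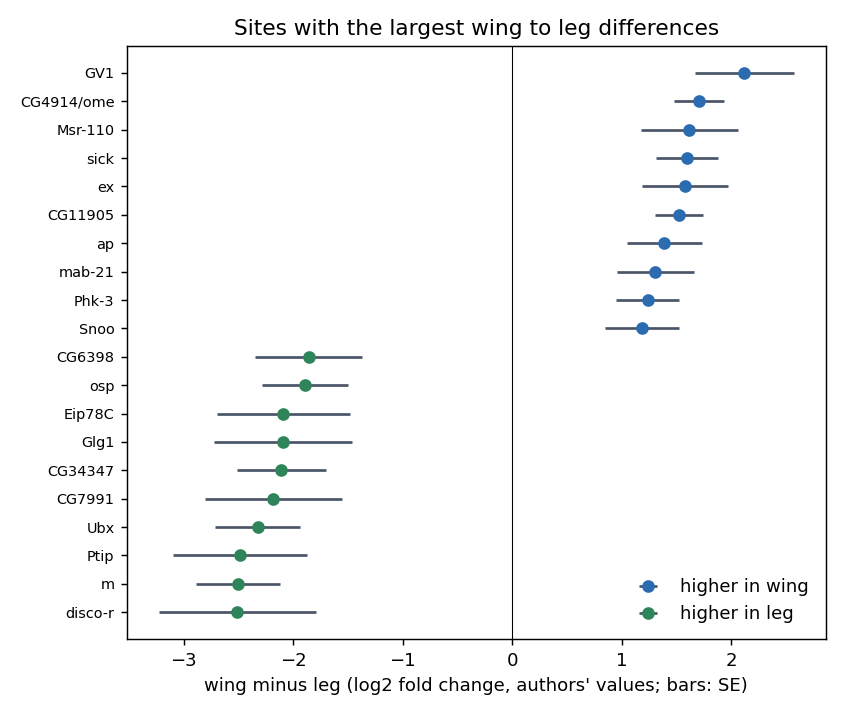
The authors' log2 fold change of wing minus leg (points, bars are standard errors) for the 10 largest called sites in each direction, 1 per gene and with a mean at or above the median of the table, each named by its gene. Sites higher in the wing (blue) run from 1.19 to 2.12 and sites higher in the leg (green) from -1.86 to -2.51.

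Sites near the centromeres and on chromosomes 4, Y and M stood apart from the arms. Of these 469 sites, 301 were higher in the wing than in the gland and 22 lower in the authors' deposited table, while the 2994 arm sites gave 692 and 892. The parts were not alike: all 5 sites on chromosome M and a cluster of 7 sites on 2R were lower in the wing. Chromosome 4 gave 5 higher and 2 lower of 17. For the leg the counts were 313 and 17 in this set and 711 and 769 on the arms, and between wing and leg 1 of the 469 was called. The arms were set apart after the data had been examined, and the ap site lies just inside the window of 2R.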

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

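All tests in this part were chosen after the result was seen, except that of the salivary gland sites near centromeres and that of fat body peaks, whose outcomes were stated before they were computed.

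The pellet lists, which the comparisons of supernatant peaks leave aside, held 773 of the 3463 sites with no supernatant peak in any tissue. Of these, 284 (36.7%, 33.3 to 40.2) lay near centromeres or on chromosomes 4, Y or M, against 185 of 2690 sites with a supernatant peak (6.88%, Fisher's exact test, two-sided, p = 4.11e-85). The test treats sites as independent, which neighbouring sites may not be. The windows were drawn after the data were examined. The lists come from merged replicates, so the p-value does not measure the spread between replicates. In another set, sites with a pellet peak and no supernatant peak in the same tissue, whatever the other tissues had, the share was 42.3% of 523 in the wing, 61.9% of 375 in the leg and 7.84% of 255 in the gland, against 132 of 1399, 97 of 1538 and 26 of 1131 sites with a supernatant peak in that tissue.

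In the authors' deposited table of wing and leg 49 sites differed, which is also a difference between the discs in their distance from the gland. Of the 30 sites higher in the leg, 24 were also higher in the leg than in the gland and none lower, while 2 were higher in the wing than in the gland and 4 lower. Of the 19 higher in the wing, 14 were higher in the wing than in the gland and 2 lower, while 4 were higher in the leg than in the gland and 4 lower. The number is small beside the 439 and 564 regions with a peak in 1 disc alone. A larger error of these fold changes is argued against, since their median standard error was 0.53 against 0.587 for wing and gland. Weak peaks near the caller's threshold remain a candidate explanation. Peaks of 1 disc alone had a lower median fold enrichment than peaks of both discs, by -2.09 in the wing list and -2.74 in the leg list (permutation test, p = 1e-05 in both, the smallest it can give). Peaks that pass the caller in 2 lists tend to be stronger by selection alone, so this cannot tell the explanations apart. A difference between the discs was tested per site in the authors' deposited table. It was called at 3 of 461 sites with a wing and no leg peak and at 25 of 600 with a leg and no wing peak. At the other sites it stays open.

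Sites near centromeres and on chromosomes 4 and Y lay higher in both discs than in the gland. Fewer reads are argued against near the centromeres of 3L and X, where the median mean normalised count was 43.3 and 103 against 9.11 on the arms (permutation test, adjusted p = 0.00035 for both over 7 parts). In the other parts it was not: the median was lower on Y (4.90, adjusted p = 0.0124), and on 2L, 3R and 4 and on 2R without a cluster of 7 gland sites it did not pass (13.5, 10.6, 8.64 and 6.91). The scaling of whole libraries stays open. It moves all sites alike, so it leaves the shift of 1.44 between these sites and the arms as it is, but which of the 2 sets is unchanged was not tested. Less DNA of these regions in the gland libraries, as in polytene nuclei that under-replicate them, remains a candidate explanation, except on chromosome Y. The tissue was labelled female, so where the reads on Y come from is not known. Less DNA in the gland predicted a shift among sites with a gland peak too. A difference in EcR binding predicts the same from the same fold changes, so the outcome cannot favour either. The permutation tests of this paragraph shuffled sites as if they were independent. All sites come from the same few libraries, so these p-values do not measure the spread between libraries. Among sites with a gland peak the shift was 2.27 (34 against 1340 sites, permutation test, p = 1e-05, the smallest it can give). That leaves out 12 sites with a gland peak, 5 on chromosome M and 7 of the 2R cluster, which lay far higher in the gland, and with them the shift was 1.05 (46 against 1340 sites, permutation test, p = 0.00012). The 2 sets also differ in how many sites are of the gland alone, and among sites with a peak in all 3 tissues, again without chromosome M and the cluster, the shift was 0.63 for the wing (25 against 380 sites, permutation test, p = 0.0591) and 1.06 for the leg (p = 0.00078), and with them 0.45 (33 against 380 sites, permutation test, p = 0.131) and 0.76 (p = 0.00835). Among sites with a peak in both discs and none in the gland it was 0.56 for the wing and 0.63 for the leg (191 against 628 sites, permutation test, p = 1e-05 for both, the smallest it can give). A difference in EcR binding between the tissues stays open, again except on chromosome Y, and was not tested.

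The gland peaks at fat body marker genes may come from fat body cells attached to the glands, which would predict weak peaks. The 4 peaks lay at a median percentile of 59.0 of fold enrichment in the gland list, from 14.2 at Lsp1beta to 80.3 at Fbp2, so the 2 sources cannot be told apart with so few peaks. How many of these genes the gland itself expresses was not tested.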

How the results depend on the processing

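Of 135 alternatives to 33 results, 84 kept the value within its bounds and 51 moved it. The side with more calls turned in all 3 comparisons when values were centred on the arms, with 45.5% of calls higher in the wing in place of 52.1% against the gland, 40.9% higher in the leg in place of 56.6%, and 73.8% higher in the wing than the leg in place of 38.8%. Why values moved was read from construction only for stricter thresholds and shorter lists, and otherwise the cause was not tested. With only peaks of a -log10 q of 10 or more the supernatant lists held 694 wing, 743 leg and 461 gland peaks, 79.5%, 42.4% and 65.5% of them overlapped a pellet peak, and the classes were 15.3% in all 3 tissues, 30.1% in wing and leg, 21.9% in the gland, 13.6% in the wing and 16.6% in the leg alone. The difference near gene ends then turned to 1.31 points from -2.14, and neither passed. With a reciprocal overlap of 50% the pellet shares were 61.0%, 29.4% and 46.9%, and the classes 7.64%, 19.0%, 27.5%, 19.3% and 23.3% in the same order. With summits within 100 bp the pellet shares were 64.6% in the wing and 53.7% in the gland, 10.4% of regions were in all 3 tissues and 17.7% in the wing alone. With equally long lists the shares were 14.4% in all 3 tissues, 32.3% in the gland, 14.5% in the wing and 14.2% in the leg alone. With pellet lists, of which the leg's holds 1010 peaks, they were 9.71% in all 3 tissues, 29.7% in the wing and 10.2% in the leg alone. With both fractions joined they were 23.6% in wing and leg, 18.1% in the wing and 18.4% in the leg alone, and on the arms alone 14.3% in the wing alone.

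An adjusted p under 0.01 left 628 sites higher in wing than gland, 635 higher in leg than gland, 11 higher in wing than leg and 9 higher in leg than wing. Sites with a mean at or above the median gave 564 higher in gland than wing, 657 higher in leg than gland and 16 higher in leg than wing. Centred on the arms, 645 were higher in leg than gland, 48 in wing than leg and 17 in leg than wing. The centring called no site in the opposite direction, and all 20 named sites of each comparison with the gland stayed called. Assigning peaks to the nearest gene end made 5 lists pass in the wing and 5 in the leg, in place of 2 and 3. Pellet lists made 4 pass in the wing and 1 in the gland, in place of 2 in each, and equally long lists 1 in the leg.

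No paired analysis was possible because the tables carry no column per library. For that reason the count test with its other tool, scaling, filter, block and left-out libraries was not run. The motif tests were not run without a genome, and gene ends replaced transcription starts throughout. Depth per library being unknown, the limit it sets on calls at weak sites is not known.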

Other observations

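The strongest signal of the gland lay on chromosome M, the mitochondrial genome. The site from 1 to 15761 on it had a mean normalised count of 74759 in the authors' deposited tables, 44.7% of the sum over sites, and log2 fold changes of -5.81 for the wing and -5.44 for the leg. On 2R, 7 sites between 5049586 and 5056313, in no coding gene span, were all higher in the gland than in both discs in the authors' deposited tables, with means of up to 5596. The 67 sites on chromosome Y, in tissue labelled female, included 24 higher in the wing and 19 higher in the leg than in the gland in the authors' deposited tables, and 0 called between wing and leg, where their median was 0.83.

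Genes beyond the ecdysone response also held sites in 1 direction in the authors' deposited tables. All 3 sites at phtm, an enzyme gene of ecdysone synthesis, were higher in both discs than in the gland (1.12 to 2.54). At E2f1, a regulator of the cell cycle, 4 of 10 sites were higher in the wing and 3 in the leg, and none in the gland, in the authors' deposited tables. Both sites at CycG were higher in the gland, from -3.44 to -2.33, in the authors' deposited tables. At srp, a factor of blood cells and fat body, 2 sites were higher in the gland than in the wing (-2.96 and -1.95) and 1 of them higher than in the leg (-1.81) in the authors' deposited tables.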
